A study of Mus musculus with 8 samples.

How the data were processed

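Affymetrix MG_U74Av2 arrays were hybridised with RNA of whole mouse colon, 1 array for each of 8 pools of 4 or 5 animals. The deposited intensity values, 1 per probe set on a linear scale from 0.03 to 12860, had been brought to a common level by the authors, since the means trimmed by 2% differed between arrays by a ratio of 1.01. The summary algorithm, the scaling target, the background correction and detection calls are not given in the sources used here. The deposited scaling was kept because that ratio lay under the limit of 1.1 set for it. Groups were read from the sample labels as strain and Il10 genotype, with 2 pools in each of 4 groups. Pools of 5 animals were those of C57BL/6J and the sample 1 pool of C3H/HeJBir Il10-null, and the other pools held 4.

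Values were analysed as log2 of the intensity plus 11.07, the 20th percentile of all values. Probe sets with a mean over the arrays of at least 37.0, the 40th percentile, were tested, which kept 7453 of 12422 probe sets, representing 5688 genes. Affymetrix control probe sets were left out. Of all probe sets, 10833 carried 1 gene symbol, 396 several and 1193 none. Of those with 1 symbol, 10817 were matched by gene number to the RefSeq table of mouse assembly GRCm38.p6, which changed 0 symbols and gave chromosomes and gene order, but no coordinates were used.

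A linear model with 4 group means and no block was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 4.23 prior degrees of freedom). It gave 7 comparisons: the Il10 effect in each strain, the difference between these effects, the strain effect in each genotype, and the average Il10 and strain effects. Strain differences are C3H/HeJBir minus C57BL/6J. Tests were two-sided, with p values adjusted by Benjamini-Hochberg over the tested probe sets and a threshold of 0.05. The p values measure the spread between pools, not between animals.

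Gene lists were written from general knowledge of cell types and pathways. They comprised 37 lists with 710 symbols, of which 544 were on the array and 382 were tested. A gene on several probe sets was read by the one with the highest mean. The 30 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Camera with a correlation estimated per list and limma's fry served as alternatives. Members were also adjusted over the list alone. The list of genes that the published study put forward (Cd14, Gbp2b and Pla2g2a) was chosen by that study on these samples. Between 2 pools and another 2, 33.3% of probe sets are fully separated by chance, and 16.7% in a given direction.

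Genes were named by a rule. For each comparison these were, among probe sets with 1 named gene, an adjusted p under the threshold and no overlap of the compared pools, the 10 with the largest log2 difference in each direction. In a direction with none, the 3 with the smallest p were named as not passing. The members of a list with the largest absolute log2 difference were named with it. Il10, Cd14, Gbp2b and Pla2g2a were always given. In the strain comparisons the tested genes listed as known to differ between the strains' genomes were given too: Nnt, Glo1 and again Gbp2b and Pla2g2a. Further probe sets of a gene were given where they disagreed. The comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, except for the alternatives without chromosomes 1, X and Y and, for gene lists, with a block on the hybridisation day.

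The experiment files gave 3 hybridisation days in 2 different years. Day 1 held the sample 1 Il10-null pools of both strains, day 2 the sample 1 wild-type pools, and day 3 the 4 sample 2 pools. Strains were therefore balanced within each day, while the Il10 genotypes were compared within a day only among the sample 2 pools. Whether the sample number paired the pools was checked by correlating, across probe sets, the deviations of the pools from their group means. The correlations ran from 0.198 to 0.332 over the 6 pairs of groups, so the sample number was used as a block in an alternative, given beside a result only where it changed a call. The block also moved p values where no call changed. It lowered the smallest limma adjusted p of the average Il10 effect from 0.623 to 0.0722 and raised that of the Il10 effect in C57BL/6J from 0.102 to 0.165.

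Each result was recomputed with pseudocounts of 2.76 and 56.7 (the 5th and 50th percentiles), without a filter, with a filter at the 60th percentile, after quantile normalization, after scaling to a common median, with trend and robust moderation, with a fit of the compared groups, with blocks on the sample number and the day, at a threshold of 0.1, with the probe sets of a gene averaged, and without each pool in turn. Gene list tests were recomputed with the alternatives that apply to them. The fit was tested on simulated data of 7453 probe sets with 200 changed. Residuals were drawn independently for each probe set and pool, without the sample number or the hybridisation day. The changed probe sets also ease the adjusted threshold, so fewer may be recovered where few probe sets differ. For the Il10 effect in C57BL/6J the fit made 128 calls, of which 6 were false. In 100 simulations of the 15 interferon-gamma-induced genes in the same comparison, a list shifted by a log2 of 1 was called in 100% with the preset and in 64% with an estimated correlation. An unshifted list was called in 1% and 0%, and an unshifted list whose members shared the deviations of the pools at a correlation of 0.624 in 39% and 0%.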

Results

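RNA from whole mouse colon was measured on 8 Affymetrix MG_U74Av2 arrays, 1 array per pool of animals. Each pool held 7 µg of RNA from each of 4 or 5 animals. The pools came from the strains C57BL/6J and C3H/HeJBir, each as wild type and as a line carrying the targeted allele Il10tm1Cgn, called Il10-null here. Il10 encodes interleukin 10, a cytokine that restrains inflammatory responses. The 4 groups of strain and genotype held 2 pools each, numbered sample 1 and sample 2 in the labels. The title of 1 pool, the sample 2 pool of C57BL/6J wild type, gives an age of 4 weeks, and the ages of the other pools and the sex of the animals are not given in the sources used here. Median intensity over the 12422 probe sets ran from 50.1 to 62.2 per array, and the number of arrays limits the precision. Values are given as mean ± SD of the 2 pools of a group, and log2 differences with the SE of the limma fit.

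Across probe sets, which are not independent replicates, the pools of a group correlated with a Spearman coefficient of 0.920 to 0.947. The sample 1 C3H/HeJBir Il10-null pool stood farthest from the rest, with a mean coefficient of 0.915 against the other 7 arrays, where the other pools had 0.931 to 0.945. The pools also differed by sample number. Xist, the RNA that coats the inactive X chromosome of female cells, read 243 to 452 in the sample 1 pools and 2.84 to 12.9 in the sample 2 pools (log2 -4.20, limma adjusted p = 0.0104). Eif2s3y, a gene of the Y chromosome, was lower in the sample 1 pool in 4 of 4 groups, with a log2 difference of 1.14 that did not pass (adjusted p = 0.147). In the sample 1 pools it read 39.7 (wild type) and 113 (Il10-null) in C57BL/6J, against 318 and 242 in C3H/HeJBir. Xist did not separate the strains there. A mix of sexes that differed between the strains in the sample 1 pools is therefore open for every strain comparison below. The 8 measured exocrine pancreas genes had a median log2 difference of -1.08, sample 2 minus sample 1 (camera adjusted p = 0.00771, and adjusted p = 0.978 with an estimated correlation). Their level, as the median log2 deviation of the members from their means over the arrays, was highest in the sample 1 C3H/HeJBir Il10-null pool, at 1.40.

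**Figure D1:**
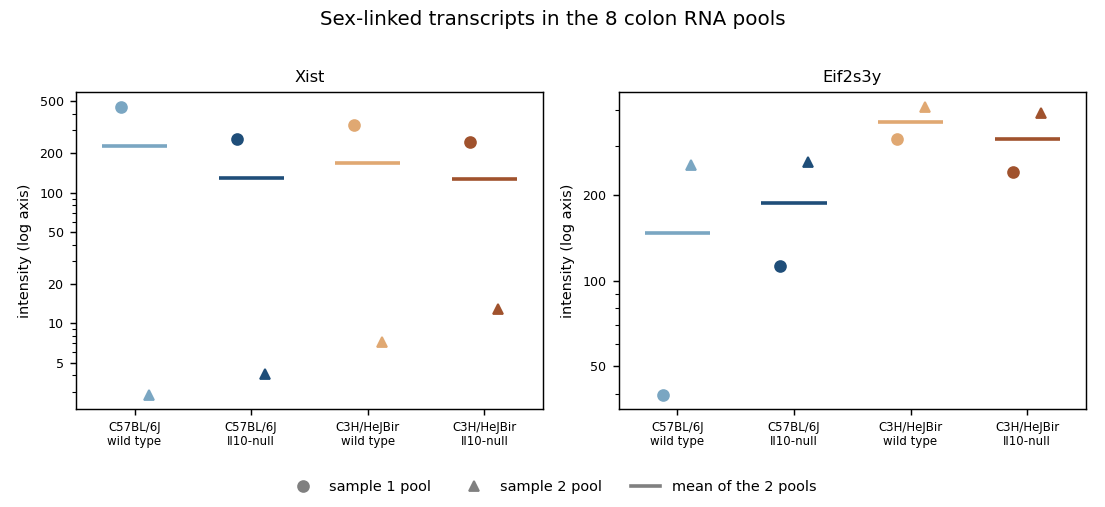
Intensity of Xist and Eif2s3y on a log axis in each of the 8 pools, with sample 1 pools and sample 2 pools marked. Xist lay between 243 and 452 in the sample 1 pools and between 2.84 and 12.9 in the sample 2 pools.

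The targeted gene itself was read by 1 probe set. Il10 read 36.9 ± 21.0 in the C57BL/6J Il10-null pools against 8.52 ± 1.67 in C57BL/6J wild type, and 31.8 ± 4.99 in the C3H/HeJBir Il10-null pools against 8.17 ± 3.87 in C3H/HeJBir wild type. Its mean over all arrays, 21.3, lay below the filter on low values, so it was not among the tested probe sets. In the fit without the filter Il10 was higher by a log2 of 1.22 ± 0.35 in C57BL/6J and 1.17 ± 0.35 in C3H/HeJBir and did not pass (limma adjusted p = 1.00 for each). Where its probes lie relative to the altered part of Il10 is not given in the sources used here, so this probe set checks no label.

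The comparison of C57BL/6J Il10-null with C57BL/6J wild-type pools asked what the loss of Il10 changed in the colon of this strain. Genes induced by interferon gamma were higher in the Il10-null pools as a group, with a median log2 difference of 1.23 over 15 members, or 2.35-fold, and a positive sign in 14 of 15 (camera adjusted p = 2.88e-13, and adjusted p = 0.638 with an estimated correlation). Adjusted over the list alone, 4 members rose (limma adjusted p = 0.0441 to 0.0464) and 11 did not pass, while over all probe sets 0 of 15 passed. Iigp1, an immunity-related GTPase, read 417 ± 358 against 46.6 ± 3.65 (log2 2.58 ± 0.71), and Ido1, an enzyme that degrades tryptophan, 162 ± 62.3 against 22.1 ± 5.98 (log2 2.34 ± 0.59). Cxcl9, a chemokine that attracts T cells, read 66.3 ± 7.52 against 8.37 ± 5.76 (log2 2.02 ± 0.64), and Gbp2, a guanylate-binding GTPase, 388 ± 138 against 117 ± 14.5 (log2 1.60 ± 0.47). In the sample 2 pools, all hybridised on 1 day, the list's median difference was 1.31, and in the sample 1 pools, whose genotypes were hybridised on different days, it was 0.34.

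The MHC class II genes, which present antigen to T cells, were higher by a median log2 of 1.23 in C57BL/6J Il10-null pools, with a positive sign in 7 of 7 (camera adjusted p = 5.06e-07, and adjusted p = 0.638 with an estimated correlation). Adjusted over the list alone, 0 of 7 passed, and the smallest limma adjusted p was 0.0505. Cd74, the invariant chain, read 1829 ± 1257 against 464 ± 91.8, and H2-DMa, which helps to load peptides, 229 ± 116 against 59.3 ± 24.7. Within the day of the sample 2 pools the class II median was 2.36, and between the sample 1 pools it was 0.38. In the sample 2 Il10-null pool adipocyte, fibroblast and smooth muscle genes had levels of -0.40, -0.30 and -0.18, as median log2 deviation. The sample 2 wild-type pool had 0.14, 0.01 and 0.19. Goblet cell and absorptive colonocyte markers moved less, at -0.02 and 0.08 against 0.03 and 0.11. The 14 acute-phase and antimicrobial genes had a median of 0.27 (camera adjusted p = 0.00443, and 0.638 with an estimated correlation). Adjusted over this list alone, 2 members rose: Retnlb, a goblet cell peptide, at 2803 ± 1740.2 against 629 ± 163 (log2 2.01 ± 0.42), and Reg3g, an antibacterial lectin, at 3205 ± 1003 against 831 ± 261 (log2 1.93 ± 0.37), while the other 12 did not pass. The median differences were 0.26 for 10 genes of MHC class I and antigen processing, 0.28 for 21 immediate early and heat shock genes, -0.28 for 11 enteroendocrine markers and -0.17 for 22 genes of drug and xenobiotic metabolism. Their camera adjusted p values were 0.000352, 0.000352, 0.00323 and 0.0174, and with an estimated correlation the adjusted p was 0.638 for each of them. Psmb8, a subunit of the immunoproteasome, read 625 ± 297 against 245 ± 31.4, and Hspa1b, a heat shock protein, 215 ± 6.80 against 124 ± 1.99. Cck, the gut hormone cholecystokinin, read 14.1 ± 9.43 against 30.1 ± 1.60, and Cyp4b1, a cytochrome P450, 217 ± 66.9 against 411 ± 139. None of these passed alone. A block on the hybridisation day ended the calls of MHC class I (median 0.27, camera adjusted p = 0.171), immediate early (0.10, 0.262), enteroendocrine (-0.22, 0.0951) and acute-phase genes (0.10, 0.171). Calls also ended without the sample 2 Il10-null pool for MHC class II (median 0.55, adjusted p = 0.301), MHC class I (0.20, 0.301), acute-phase (0.14, 0.220), enteroendocrine (-0.21, 0.187) and xenobiotic genes (-0.08, 0.333). Without the sample 2 wild-type pool they ended for acute-phase (0.04, 0.108), enteroendocrine (-0.17, 0.159) and xenobiotic genes (-0.18, 0.183). Over all alternatives of the 7 lists the adjusted p ranged from 1.67e-20 to 0.925.

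No single probe set passed in C57BL/6J: limma called 0 of 7453, with 118 at an unadjusted p under 0.05, where uniform p values would give 373. That count is no baseline for this model, whose spread takes in the difference between sample numbers. A count below it does not show that nothing changed, and one slightly above it does not show that little did. In simulated data for this comparison, 15% of probe sets changed by a log2 of 1 and 92.5% of those changed by 2 were recovered. The smallest adjusted p, 0.102, belonged to a probe set without a gene symbol (limma). Among probe sets with a symbol, Gga2, an adaptor of vesicle transport, had a log2 difference of 1.56 ± 0.26 (limma adjusted p = 0.705). Vcam1, an adhesion molecule of inflamed vessels, read 61.0 ± 4.29 against 18.2 ± 2.37 (adjusted p = 0.705), and Reg3b, an antibacterial lectin, 4348 ± 1273 against 1361 ± 23.9. A brighter probe set of Reg3b gave a log2 of 0.44 where this one gave 1.64, and another probe set of Vcam1 gave -0.03 where this one gave 1.30. In the other direction, Dusp2, a phosphatase of activated lymphocytes, read 25.4 ± 17.2 against 107 ± 18.8, and Cox6b1, a subunit of the respiratory chain, 40.2 ± 25.2 against 106 ± 20.8. Igfbp7 had a log2 difference of -0.90 ± 0.25. The genes that the published study put forward from these samples, which are not independent evidence, read 521 ± 50.3 against 343 ± 2.03 for Cd14, 15.7 ± 13.6 against 11.6 ± 11.3 for Gbp2b and 33.0 ± 16.8 against 25.4 ± 26.8 for Pla2g2a, and 0 of 3 passed (limma adjusted p = 1.00).

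**Figure D2:**
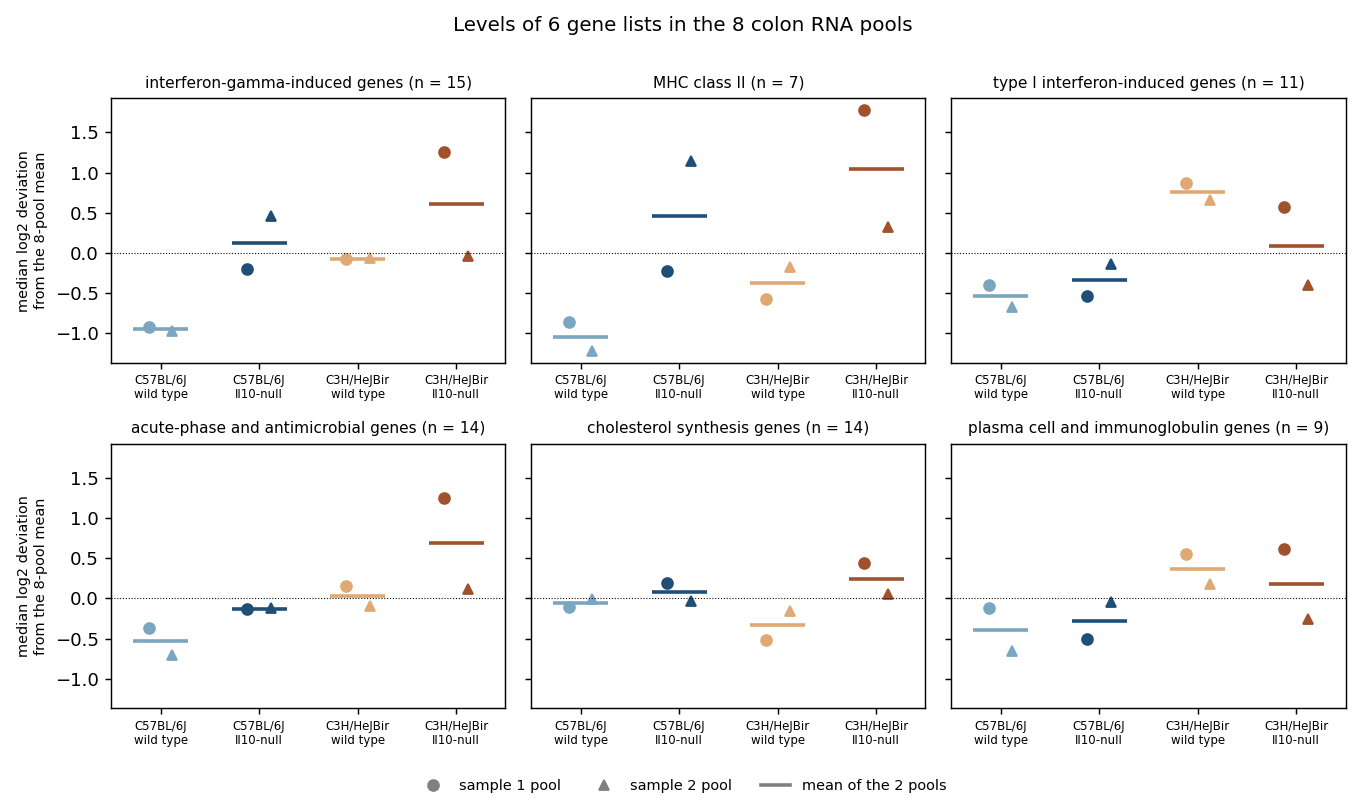
Level of gene lists in each of the 8 pools, as the median over each list's members of the log2 deviation from the member's mean over the arrays. The level of genes induced by interferon gamma was 1.25 in the sample 1 C3H/HeJBir Il10-null pool and -0.04 in the sample 2 pool, against -0.20 and 0.46 in the C57BL/6J Il10-null pools.

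The same comparison in C3H/HeJBir gave 1 probe set that passed. Gas5, a noncoding RNA that hosts small nucleolar RNAs, rose from 103 ± 23.5 in wild type to 1147 ± 414 in Il10-null pools (log2 3.31 ± 0.33, limma adjusted p = 0.0450). The difference was 3.15 in the sample 1 and 3.47 in the sample 2 pools. The C57BL/6J pools read 1213 ± 209.6 in wild type and 1175 ± 249.6 in Il10-null. The other probe set of Gas5 gave a log2 of 1.29 and did not pass (adjusted p = 0.999). The Gas5 call ended with a block on the hybridisation day (log2 3.41, adjusted p = 0.132) and without each of 7 of the 8 pools, the sample 2 C3H/HeJBir Il10-null pool being the exception. Over all alternatives the log2 value ran from 2.30 to 3.68 and the adjusted p from 0.00252 to 0.778. At an unadjusted p under 0.05 there were 211 probe sets of 7453, where uniform p values would give 373. In simulated data, which lacked the structure of sample numbers and days, 95% of probe sets changed by a log2 of 2 were recovered. The smallest p among lower probe sets belonged to Btg2, an antiproliferative immediate early gene, at 342 ± 23.9 against 848 ± 104, Tor3a, an ATPase of the torsin family, at 82.5 ± 10.2 against 213 ± 33.3, and Ifi27l2a, induced by interferon, at 191 ± 9.40 against 442 ± 41.4, and none passed (limma adjusted p = 0.999). Cd14 read 3084 ± 1055 against 1788 ± 131, Gbp2b 519 ± 349 against 240.1 ± 15.1 and Pla2g2a 3365 ± 2944 against 1592 ± 594, and these 3 genes, which the study chose on these samples, did not pass.

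Genes of cholesterol synthesis were higher as a group in the C3H/HeJBir Il10-null pools, by a median log2 of 0.53 over 14 members with a positive sign in 12 (camera adjusted p = 1.17e-07, and 0.606 with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, read 106 ± 46.6 against 41.9 ± 2.09, Fdft1, squalene synthase, 704 ± 208 against 373 ± 116, and Sqle, squalene epoxidase, 792 ± 234 against 416 ± 70.5. Interferon-gamma-induced genes were higher by a median of 0.75 over 15 members (adjusted p = 1.54e-06) and MHC class II genes by 1.40 over 7 (adjusted p = 8.54e-06), with an adjusted p of 0.606 for each with an estimated correlation. Iigp1 read 609.6 ± 456 against 114 ± 58.9, and H2-DMb1, which helps to load peptides, 418 ± 364 against 86.0 ± 26.2. Genes induced by type I interferon, which belong to antiviral defence, were lower by a median of -0.67 over 11 members with a negative sign in 9 (adjusted p = 8.54e-06, and 0.606 with an estimated correlation). Adjusted over the list alone, 1 of these 11 fell, Ifi27l2a (log2 -1.16 ± 0.26, limma adjusted p = 0.0206), and Isg15, a ubiquitin-like protein, read 316 ± 279 against 698 ± 105. In the other lists called in this comparison 0 members passed.

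Acute-phase and antimicrobial genes had a median log2 of 0.34 over 14 members (camera adjusted p = 0.000966), MHC class I and antigen processing genes 0.35 over 10 (0.00552), drug and xenobiotic metabolism genes -0.28 over 22 (0.00861), enteroendocrine markers -0.29 over 11 (0.0165) and T cell and NK cell markers 0.27 over 6 (0.0165). With an estimated correlation the adjusted p was 0.606 for each of these. S100a8, a neutrophil protein, read 295 ± 404 against 28.1 ± 8.41, and Abcb1a, a drug efflux pump, 845 ± 613 against 1361 ± 112. Sst, the hormone somatostatin, read 66.4 ± 59.8 against 113 ± 22.3, and Gzmb, a protease of cytotoxic cells, 56.4 ± 28.6 against 23.5 ± 3.62. In the sample 1 Il10-null pool other lists stood apart as well, with levels of -0.55 for smooth muscle, -0.33 for fibroblast, -0.30 for goblet cell, -0.37 for small intestinal and Paneth cell, 1.30 for neutrophil and 1.40 for exocrine pancreas genes, as median log2 deviation. Between the sample 1 pools the median differences were 1.32 for interferon-gamma-induced, 2.29 for MHC class II, 0.76 for cholesterol synthesis and -0.46 for type I interferon-induced genes, and within the day of the sample 2 pools they were 0.04, 0.50, 0.25 and -1.12. Without the sample 1 Il10-null pool the calls ended for interferon-gamma-induced genes (median -0.07, camera adjusted p = 0.884), MHC class II (0.66, 0.0741), MHC class I (-0.04, 0.982), acute-phase (0.02, 0.797), T and NK cell (-0.00, 0.997), enteroendocrine (0.01, 0.797) and xenobiotic genes (-0.14, 0.399). Without the sample 2 Il10-null pool that of type I interferon-induced genes ended (-0.21, 0.755). Without the sample 1 wild-type pool the MHC class I (0.40, 0.101) and T and NK cell calls (0.41, 0.0861) ended. Without the sample 2 wild-type pool those of acute-phase (median 0.30), T and NK cell (0.31), enteroendocrine (-0.24) and xenobiotic genes (-0.27) ended. A block on the hybridisation day ended those of MHC class I (median 0.27, camera adjusted p = 0.183), T and NK cell (0.09, 0.294) and enteroendocrine genes (-0.27, 0.157). Over all alternatives of the 9 lists the adjusted p ranged from 4.02e-19 to 0.997.

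Il10 lies on chromosome 1, as do Gas5, Btg2 and Tor3a. The C3H/HeJBir comparison was also read by chromosome, and the count on chromosome 1 includes the probe sets of these genes. At an unadjusted p under 0.05 stood 18 of 354 tested probe sets on chromosome 1 (5.08%) and 172 of 6363 on the other chromosomes (2.70%), an odds ratio of 1.93 (Fisher's exact test, two-sided, p = 0.0131). Chromosome 1 was not alone in this, since the share was 5.15% on chromosome 8 (19 of 369) and 4.66% on chromosome 7 (24 of 515). In C57BL/6J the odds ratio was 0.906 (Fisher's exact test, p = 1). Gas5, Tor3a and Qsox1, a sulfhydryl oxidase, read in the C3H/HeJBir Il10-null pools close to the C57BL/6J wild-type level: Tor3a at 82.5 against 84.9 and Qsox1 at 169 against 184, where C3H/HeJBir wild type read 213 and 45.4. Of the 18 probe sets of chromosome 1, 14 (77.8%) lay closer to C57BL/6J wild type than to C3H/HeJBir wild type in the Il10-null pools, and so did 124 of the 172 elsewhere (72.1%). Other genes of chromosome 1 kept the strain difference in the Il10-null pools, among them Snhg6, Rgs5, Mptx1 and Ifi202b. Gas5, Tor3a and Qsox1 were chosen for their pattern after the values were seen, so they are no evidence for an excess of it on this chromosome.

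**Figure D3:**
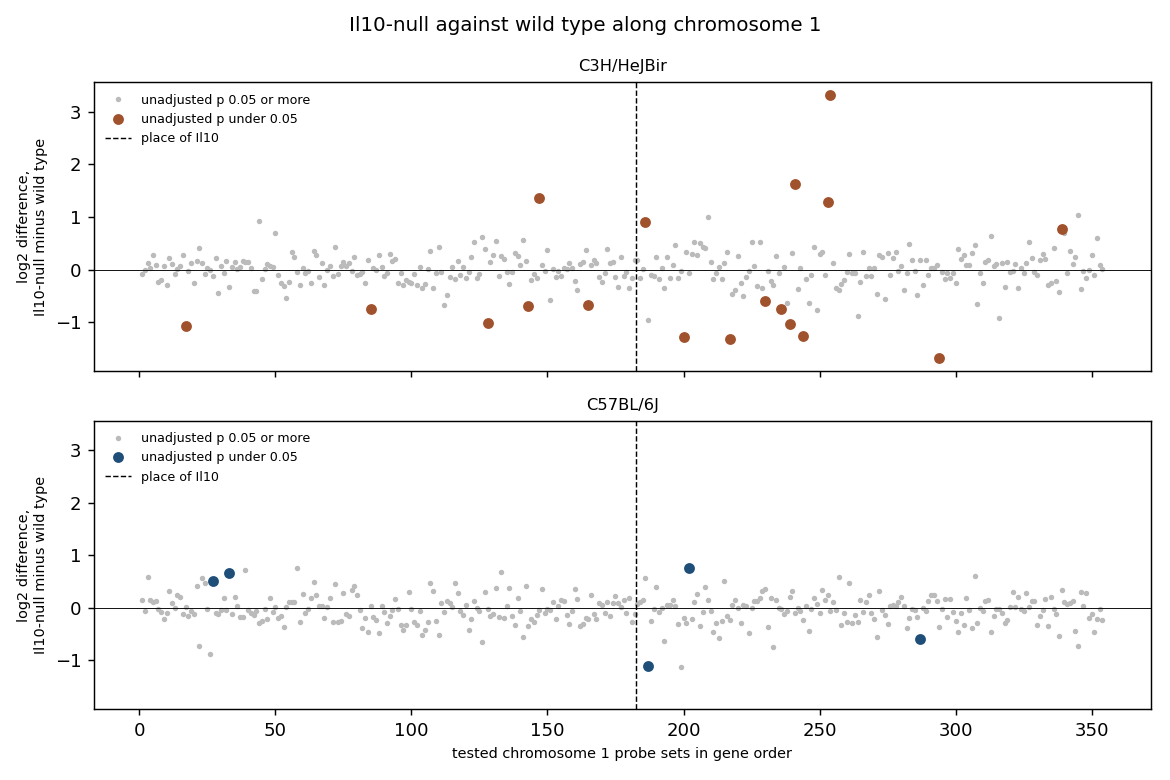
Log2 difference between Il10-null and wild-type pools for each tested probe set of chromosome 1, in gene order along the chromosome, in C3H/HeJBir and in C57BL/6J, with the place of Il10 marked. Gas5 reached 3.31 in C3H/HeJBir.

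The difference between the Il10 effects of the strains, C3H/HeJBir minus C57BL/6J, asked whether the strain changes the response to the loss of Il10. Genes induced by type I interferon differed by a median log2 of -0.98 over 11 members, with a negative sign in 10 (camera adjusted p = 0.000139, and adjusted p = 0.995 with an estimated correlation). Isg15 read 698 ± 105 in C3H/HeJBir wild type, 316 ± 279 in C3H/HeJBir Il10-null, 139 ± 28.4 in C57BL/6J wild type and 208 ± 73.5 in C57BL/6J Il10-null pools (difference -1.96 ± 0.82), and Ifi27l2a had a difference of -1.33 ± 0.37. Genes of cholesterol synthesis differed by a median of 0.45 over 14 members, with a positive sign in 11 (camera adjusted p = 0.000630, and adjusted p = 0.995 with an estimated correlation). Mvd had a difference of 1.07 ± 0.55 and Lss, lanosterol synthase, of 0.96 ± 0.40. Adjusted over each list alone, 0 members passed. Between the sample 1 pools the medians were -0.14 and 0.54, and within the day of the sample 2 pools -1.63 and 0.26. The type I interferon call ended without the sample 2 C57BL/6J Il10-null pool (-0.65, adjusted p = 0.104) and without the sample 2 C3H/HeJBir Il10-null pool (-0.11, 0.383). The cholesterol call ended without the sample 2 C57BL/6J wild-type (0.39, 0.0772), sample 2 C57BL/6J Il10-null (0.37, 0.0995), sample 1 C3H/HeJBir wild-type (0.32, 0.185) or sample 1 C3H/HeJBir Il10-null pool (0.24, 0.140). Over all alternatives the adjusted p ranged from 4.92e-15 to 0.995 and from 0.000141 to 0.995.

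No probe set passed for this difference: limma called 0 of 7453, with 112 at an unadjusted p under 0.05, where uniform p values would give 373. The smallest limma adjusted p, 0.480, belonged to Gas5 (3.36 ± 0.46) and to a probe set without a gene symbol. In simulated data for this comparison, again without sample number or day, 2.5% of probe sets changed by a log2 of 1 and 62.5% of those changed by 2 were recovered. Qsox1 had a difference of 1.71 ± 0.42 on 1 probe set and -0.01 on another, and Dusp2 of 2.47 ± 0.64. In the other direction stood Gga2 (-1.93 ± 0.36), Chrne, a subunit of the acetylcholine receptor (-2.19 ± 0.44), and Vcam1 (-1.39 ± 0.31, and 0.50 on another probe set). Cd14 (0.16 ± 0.39), Gbp2b (0.67 ± 0.79) and Pla2g2a (0.33 ± 1.05) did not pass.

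The comparison of wild-type pools asked how the colon of C3H/HeJBir differed from that of C57BL/6J without the targeted allele. Of 7453 probe sets, 16 were higher and 14 lower in C3H/HeJBir (limma), with 423 at an unadjusted p under 0.05, where uniform p values would give 373. The largest difference among the higher probe sets was that of Pdxdc1, a decarboxylase domain protein (log2 6.56 ± 0.32, adjusted p = 8.91e-05). Pla2g2a, a secreted phospholipase that is inactivated by mutation in C57BL/6 mice, was higher at 1592 ± 594 against 25.4 ± 26.8 (log2 5.64 ± 0.74, adjusted p = 0.0160), Itln1, a lectin that binds microbial sugars, at 1707 against 64.2 (4.51 ± 0.53, 0.00956), and Retnlb at 10152 ± 1116 against 629 ± 163 (4.01 ± 0.42, 0.00640). Slpi, a secreted inhibitor of proteases, was higher at 2044 ± 329 against 127 ± 9.04 (3.89 ± 0.38, 0.00517), Mmp7, a matrix metalloproteinase, at 149.9 ± 48.9 against 6.43 ± 0.841 (3.17 ± 0.28, 0.00404), and Mptx1, a mucosal pentraxin, at 5886 ± 209.5 against 714 ± 33.8 (3.02 ± 0.34, 0.00949). Cd14, a receptor for bacterial lipopolysaccharide, was higher at 1788 ± 131 against 343 ± 2.03 (2.34 ± 0.28, 0.00956), and the interferon-induced genes Gbp2b and Ifi202b by 3.56 ± 0.56 (0.0468) and 2.62 ± 0.31 (0.00965). Gbp2b lost its call with the sample number as a block (adjusted p = 0.0891). Pla2g2a, Cd14 and Gbp2b were chosen by the study on these samples, and all 3 passed in this model. A block on the hybridisation day ended the calls of Pla2g2a (adjusted p = 0.0665), Cd14 (0.0653) and Gbp2b (0.203). It left their log2 differences unchanged, since the strains were balanced within days. The block also leaves fewer residual degrees of freedom, so these lost calls do not show an effect of the day. Several of these genes had C57BL/6J readings near or below the 11.07 added before the logarithm, so their log2 sizes depend on it. Over the alternatives they ran from 1.69 to 4.02 for Mmp7, from 1.13 to 3.91 for Ifi202b, from 2.13 to 4.35 for Gbp2b and from 4.32 to 6.47 for Pla2g2a. With 2.76 added the call of Gbp2b ended. The size of Pdxdc1 depends on it as well.

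**Figure D4:**
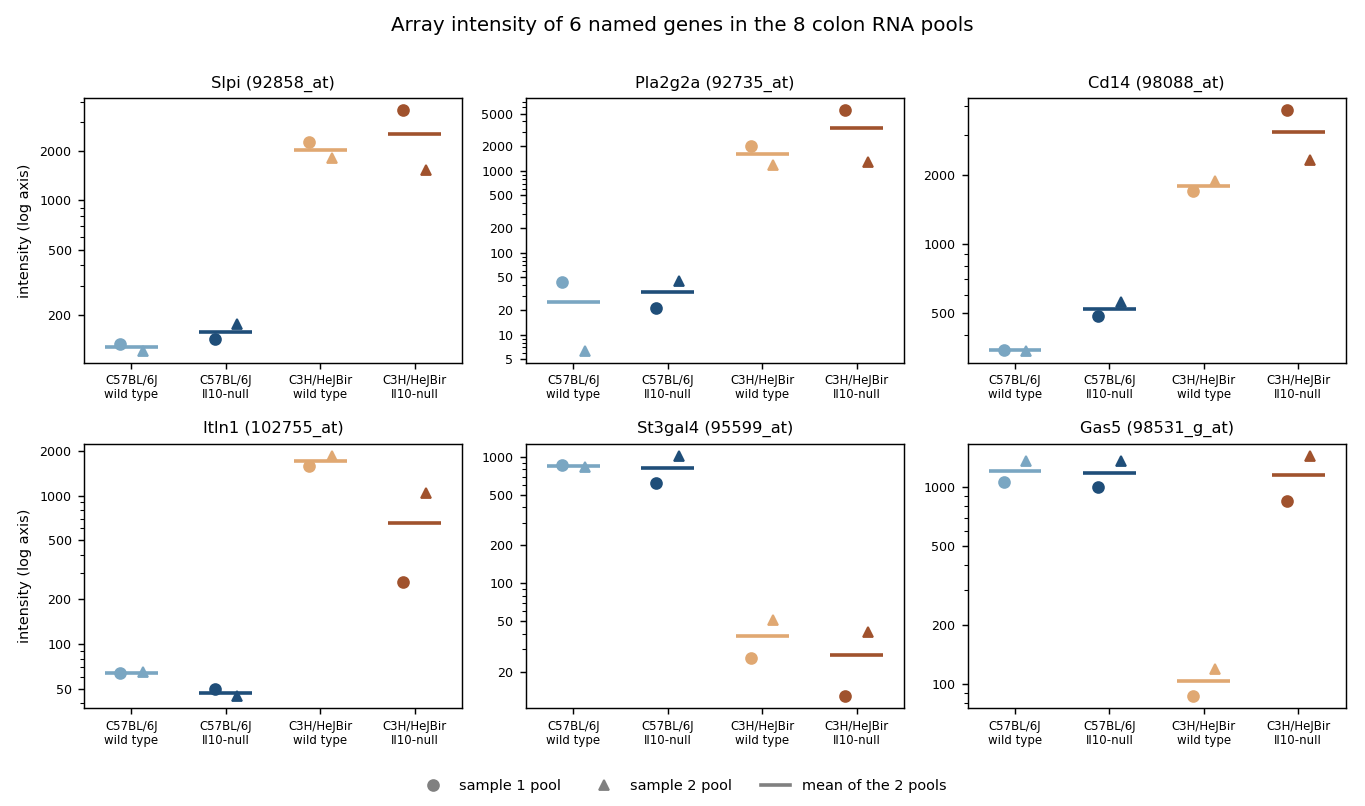
Intensity of Slpi, Pla2g2a, Cd14, Itln1, St3gal4 and Gas5 on a log axis in each of the 8 pools, as circles for sample 1, triangles for sample 2 and a bar for the mean of the 2 pools. Slpi had a mean of 127 in C57BL/6J and 2044 in C3H/HeJBir wild type, and St3gal4 847 and 38.1.

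Lower in C3H/HeJBir wild type were St3gal4, a sialyltransferase, at 38.1 ± 18.0 against 847 ± 15.8 (log2 -4.17 ± 0.43, limma adjusted p = 0.00640), and B4galnt2, which adds N-acetylgalactosamine to glycans, at 152 ± 10.1 against 911 ± 162 (-2.49 ± 0.30, 0.00977). The noncoding RNAs Gas5 (-3.43 ± 0.33, 0.00517), Meg3 (-3.22 ± 0.49, 0.0382) and Snhg6 (-2.50 ± 0.30, 0.00977) were lower too. So were Mtmr7 (-2.63 ± 0.22, 0.00404), Prdx2, a peroxiredoxin (-2.58 ± 0.34, 0.0160), Rgs5, a regulator of G protein signalling (-2.41 ± 0.28, 0.00956), and a probe set annotated to Mir686 (-2.36 ± 0.31, 0.0157), which on this type of array need not read the microRNA itself. A block on the day ended the calls of Snhg6 (adjusted p = 0.0653), Meg3 (0.0763), Prdx2 (0.0950) and the Mir686 probe set (0.0781), with unchanged log2 differences. That of Meg3 also ended with 2.76 added before the logarithm. Mtmr7 read 3.61 in C3H/HeJBir, less than the added 11.07, and its log2 size ran from -3.72 to -1.18 over the alternatives. Pdxdc1 was higher on 1 probe set, at 2292 ± 214 against 14.1 ± 9.57, and lower on another 2, by -2.86 ± 0.25 and -2.70 ± 0.31. Prdx2 on its other probe set gave -0.13, Rgs5 -0.56, Gas5 -0.82 and B4galnt2 -0.90, and Slpi gave 3.25, -0.08 and -0.01 on its other 3. Among genes known to differ between the strains' genomes, Nnt, a mitochondrial transhydrogenase that carries a deletion in C57BL/6J, read 105 ± 53.0 against 41.0 ± 1.85 and Glo1, whose copy number differs between inbred strains, 1089 ± 139.6 against 435 ± 75.6, and neither passed here (adjusted p = 0.606 and 0.134). The count of calls fell to 2 without either C57BL/6J wild-type pool, to 8 without the sample 1 and to 9 without the sample 2 C3H/HeJBir wild-type pool. Of 20 named probe sets past the threshold, 1 kept its call without each of the 8 pools in turn, that of Pdxdc1 on its higher probe set, and limma recovered 92.5% of probe sets changed by a log2 of 2 in simulated data.

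As groups, genes induced by type I interferon were higher in C3H/HeJBir wild type, by a median log2 of 1.36 over 11 members, all with a positive sign (camera adjusted p = 1.95e-11, and adjusted p = 0.803 with an estimated correlation). Adjusted over the list alone, 7 of the 11 were higher and 4 did not pass. They included Isg15 at 698 ± 105 against 139 ± 28.4 and Ifit1, which binds viral RNA, at 544 ± 78.6 against 154 ± 69.1. These C3H/HeJBir wild-type pools are also the controls of the C3H/HeJBir Il10 comparison and of the difference between the strains, in which this list had negative medians. Acute-phase and antimicrobial genes had a median of 0.38 and a mean of 1.31 over 14 members (camera adjusted p = 1.69e-07, and adjusted p = 0.803 with an estimated correlation). Adjusted over this list alone, 4 were higher, Pla2g2a, Retnlb, Slpi and Reg3g, and over all probe sets 3 passed. Interferon-gamma-induced genes were higher by 0.85 over 15 members (camera adjusted p = 3.77e-07, and adjusted p = 0.947 with an estimated correlation), with 2 higher over the list alone, Gbp2b and Gbp3. Gbp2b, like Pla2g2a of the acute-phase list, is also listed among the genes known to differ between the strains' genomes. Plasma cell and immunoglobulin genes were higher by 0.67 over 9 members (camera adjusted p = 2.22e-05, and adjusted p = 0.803 with an estimated correlation), with 3 higher over the list alone. Of these, Ighg3, an immunoglobulin heavy chain, read 547 ± 156 against 16.0 ± 2.39 and Igha, the heavy chain of IgA, 2412 ± 235 against 652 ± 341. MHC class I and antigen processing genes were higher by 0.40 over 10 members (camera adjusted p = 0.0344, and adjusted p = 0.947 with an estimated correlation). This call ended with the sample number as a block (adjusted p = 0.0817), with a block on the day (0.102), without the sample 1 C57BL/6J wild-type pool (0.46, 0.172) and without the sample 2 C3H/HeJBir wild-type pool (0.43, 0.228). Over all alternatives of the 5 lists the adjusted p ranged from 8.83e-15 to 0.947. The medians ran from 0.23 to 1.13 for plasma cell and from 0.28 to 0.64 for acute-phase genes. On the day of the sample 1 wild-type pools the medians of the 5 lists were 1.31, 0.58, 0.86, 0.81 and 0.35, and on the day of the sample 2 pools 1.43, 0.66, 0.77, 0.53 and 0.38.

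The Il10-null pools of the strains, which share no pool with the wild-type comparison, gave 12 probe sets higher and 10 lower in C3H/HeJBir (limma). At an unadjusted p under 0.05 there were 385, where uniform p values would give 373, which is no baseline for this model. Of the 22 called, 20 were also called among the wild-type pools, all with the same sign. The lists are not independent, since both comparisons used the residual variance of the same fit. Slpi was higher at 2539 ± 1417 against 158 ± 23.5 (log2 3.80 ± 0.38, limma adjusted p = 0.00604), Mmp7 at 267 ± 58.9 against 12.2 ± 0.205 (3.56 ± 0.28, 0.00271), Pla2g2a at 3365 ± 2944 against 33.0 ± 16.8 (5.97 ± 0.74, 0.0186) and Cd14 at 3084 ± 1055 against 521 ± 50.3 (2.50 ± 0.28, 0.0112). Gbp2b (4.23 ± 0.56, 0.0217), Mptx1 (2.65 ± 0.34, 0.0192), Ifi202b (2.49 ± 0.31, 0.0188), Cap1, an actin-binding protein (2.21 ± 0.26, 0.0164), Hebp1, a heme-binding protein (1.70 ± 0.25, 0.0420), and Pdxdc1 on 1 probe set (6.15 ± 0.32, 0.000282) were higher as well. St3gal4 was lower at 26.9 ± 20.1 against 819 ± 284 (-4.51 ± 0.43, 0.00595) and Ybx1, a protein that binds RNA, at 1110.1 ± 126 against 4621 ± 93.9 (-2.05 ± 0.22, 0.00964). Ctsc, a lysosomal protease, was lower by -2.59 ± 0.33 (0.0192) with 0.19 on another probe set, and so were Mtmr7 (-2.53 ± 0.22, 0.00364), Snhg6 (-2.47 ± 0.30, 0.0179), Rgs5 (-2.17 ± 0.28, 0.0199), Ergic1 (-2.16 ± 0.32, 0.0436) and Pdxdc1 on another probe set (-2.85 ± 0.25, 0.00364). On other probe sets Rgs5 gave -0.48 and Slpi 3.45, 0.43 and 0.50.

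Itln1 read 649 ± 549 against 47.2 ± 3.76 and Gas5 1147 ± 414 against 1175 ± 249.6 in the Il10-null pools. Nnt read 86.0 ± 4.47 against 127 ± 45.1 and Glo1 1183 ± 49.0 against 461 ± 108 (limma adjusted p = 0.118), and neither passed. With the sample number as a block, the calls of Gbp2b and Ergic1 ended (adjusted p = 0.0518 for each). With a block on the day the count fell from 22 to 6, of which 5 were shared. This ended the calls (adjusted p = 0.0502 to 0.143) of Pla2g2a, Gbp2b, Slpi, Mptx1, Cd14, Ifi202b, Cap1, Hebp1, Ctsc, Snhg6, Rgs5, Ergic1, Ybx1 and the lower probe set of Pdxdc1, while their log2 differences stayed the same. Ifi202b in C57BL/6J and Ctsc and Mtmr7 in C3H/HeJBir read less than the 11.07 added before the logarithm. With 2.76 added in its place the calls of Pla2g2a, Gbp2b, Ifi202b, Hebp1, Ctsc and Ergic1 ended, and with 56.7 added that of Hebp1. The count was 8 without the sample 1 and 4 without the sample 2 C57BL/6J Il10-null pool, and 34 without the sample 2 C3H/HeJBir Il10-null pool. Of 18 named probe sets past the threshold, 2 kept their call without each of the 8 pools in turn, Mmp7 and the higher probe set of Pdxdc1, and limma recovered 90% of probe sets changed by a log2 of 2 in simulated data.

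As groups among the Il10-null pools, acute-phase and antimicrobial genes were higher in C3H/HeJBir by a median log2 of 0.75 over 14 members, all with a positive sign (camera adjusted p = 1.63e-10, and adjusted p = 0.768 with an estimated correlation). Over all alternatives this median ran from 0.27 to 1.12. The list's level, as median log2 deviation, was 1.25 in the sample 1 and 0.12 in the sample 2 C3H/HeJBir Il10-null pool. Adjusted over the list alone, 3 were higher, Pla2g2a, Slpi and Retnlb, and over all probe sets 2 passed. Interferon-gamma-induced genes were higher by 0.52 over 15 members (camera adjusted p = 0.00299, and 0.774 with an estimated correlation), with Gbp2b the 1 member to pass, and macrophage and dendritic cell markers by 0.34 over 15 (0.00299, and 0.768), with Cd14 the 1 member to pass. Gbp2b is also listed among the genes known to differ between the strains' genomes. Lyz2, the lysozyme of macrophages, read 409 ± 151 against 179 ± 105. Type I interferon-induced genes were higher by 0.29 over 11 members (camera adjusted p = 0.0115, and 0.774 with an estimated correlation), plasma cell and immunoglobulin genes by 0.42 over 9 (0.0329, and 0.774), and immediate early and heat shock genes were lower by -0.23 over 21 (0.0115, and 0.768), with Btg2 the 1 member to fall over the list alone (-1.05 ± 0.23). On the day of the sample 1 Il10-null pools the interferon-gamma and type I interferon medians were 1.62 and 1.15, and on the day of the sample 2 pools -0.56 and -0.12. Calls ended without the sample 1 C3H/HeJBir Il10-null pool for interferon-gamma-induced (median -0.17, adjusted p = 0.284), type I interferon-induced (-0.24, 0.464), plasma cell (-0.02, 0.812) and macrophage genes (0.17, 0.184), and without the sample 2 pool of that group for immediate early genes (-0.10, 0.444). Without the sample 1 C57BL/6J Il10-null pool calls ended for interferon-gamma-induced (0.06, 0.341), type I interferon-induced (0.16, 0.341), plasma cell (0.16, 0.341), macrophage (0.33, 0.103) and immediate early genes (-0.17, 0.103). The plasma cell call also ended with the sample number as a block (0.0692) and with the day as a block (0.0844). Over all alternatives of the 6 lists the adjusted p ranged from 7.36e-12 to 0.924.

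Averaged over the strains, the Il10 effect asked how the lines lacking Il10 differed from wild type on average, which need not hold in each strain. The type I interferon and cholesterol lists below were called as differing between the strains, with C57BL/6J medians of 0.07 and 0.08. Interferon-gamma-induced genes were higher by a median log2 of 0.79 over 15 members (camera adjusted p = 1.46e-14, and 0.40 with an estimated correlation), with 4 higher over the list alone: Iigp1 (2.38 ± 0.50), Ido1 (2.03 ± 0.42), Cxcl9 (1.63 ± 0.45) and Gbp2 (1.18 ± 0.33). MHC class II genes were higher by 1.45 over 7 (4.46e-09, and 0.40 with an estimated correlation), also with 4 higher over the list alone: Cd74 (1.70 ± 0.41), H2-DMb1 (1.67 ± 0.50), H2-DMa (1.56 ± 0.37) and H2-Aa (1.45 ± 0.47). The medians within the day of the sample 2 pools were 0.71 and 1.51, and between the sample 1 pools 1.18 and 1.39. Acute-phase and antimicrobial genes were higher by 0.40 over 14 (1.96e-05, and 0.40 with an estimated correlation), with Reg3g the 1 member to rise over the list alone (1.46 ± 0.26). MHC class I and antigen processing genes were higher by 0.33 over 10 (1.83e-05), cholesterol synthesis genes by 0.29 over 14 (3.81e-06) and immediate early and heat shock genes by 0.14 over 21 (0.00410), of which Btg2 fell over the list alone (-0.73 ± 0.16). With an estimated correlation the adjusted p of these 3 lists was 0.40. Enteroendocrine markers were lower by -0.32 over 11 (0.000210), drug and xenobiotic metabolism genes by -0.21 over 22 (0.000388) and type I interferon-induced genes by -0.31 over 11 (0.00515), with adjusted p values of 0.40, 0.40 and 0.512 with an estimated correlation. B cell markers were lower by -0.28 over 8 (0.0362), adipocyte markers by -0.23 over 10 (0.0372) and fatty acid oxidation and ketogenesis genes by -0.17 over 15 (0.0378), with an adjusted p of 0.512 for each with an estimated correlation. Cd79a, a part of the B cell receptor, had a difference of -1.17 ± 0.38.

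A block on the day ended the average calls of MHC class I (median 0.29, camera adjusted p = 0.0544), B cell (-0.13, 0.124), immediate early (0.05, 0.936), fatty acid oxidation (-0.09, 0.520) and cholesterol synthesis genes (0.08, 0.567). Over all alternatives of the 12 lists the adjusted p ranged from 3.12e-19 to 0.936. Leaving out 1 pool ended no call of interferon-gamma-induced, MHC class I, MHC class II, xenobiotic or cholesterol synthesis genes, but it changed their size. Without the sample 1 C3H/HeJBir Il10-null pool the medians were 0.35 for interferon-gamma-induced and 0.18 for MHC class I genes, and over all alternatives that of MHC class II ran from 0.97 to 1.86. Leaving out 1 pool did end the call of acute-phase (0.05, adjusted p = 0.114) and enteroendocrine genes (-0.15, 0.0621) without the sample 1 C3H/HeJBir Il10-null pool, and that of type I interferon-induced genes without the sample 1 C57BL/6J (-0.26, 0.241) or sample 2 C3H/HeJBir Il10-null pool (0.05, 0.831). Immediate early genes lost theirs without the sample 1 C3H/HeJBir wild-type (0.10, 0.145) or Il10-null pool (0.10, 0.106). The B cell, adipocyte and fatty acid oxidation calls ended without each of 5, 4 and 4 pools, with adjusted p up to 0.816, 0.705 and 0.766. With the probe sets of a gene averaged the adipocyte and fatty acid oxidation calls ended as well. No probe set passed for the average: limma called 0 of 7453, with 230 at an unadjusted p under 0.05, where uniform p values would give 373. Without the sample 2 C3H/HeJBir Il10-null pool 11 were called. The smallest adjusted p, 0.623, belonged to Gas5 (1.63 ± 0.23), Reg3b (1.31 ± 0.21, with 0.42 on its brighter probe set) and a probe set without a gene symbol. Reg3g had 1.46 ± 0.26 (0.723), and Dio1, a deiodinase of thyroid hormone, Tor3a and Btg2 had -0.68 ± 0.18, -0.74 ± 0.18 and -0.73 ± 0.16. Cd14 (0.66 ± 0.20), Gbp2b (0.57 ± 0.40) and Pla2g2a (0.61 ± 0.52) did not pass.

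Averaged over the genotypes, 31 probe sets were higher and 52 lower in C3H/HeJBir (limma), with 628 at an unadjusted p under 0.05, where uniform p values would give 373. With a block on the hybridisation day 64 were called, of which 60 were among these 83. The sign was the same on all 3 days for 82 of the 83, which were chosen on the same pools. The higher genes with the largest differences, whose order depends on the value added before the logarithm, were Pdxdc1 on 1 probe set, Pla2g2a, Gbp2b, Itln1 (3.85 ± 0.37, adjusted p = 0.00182), Slpi, Mmp7, Retnlb (3.03 ± 0.30, 0.00182), Mptx1, Ifi202b and Cd14, between 6.36 and 2.42. The lower genes were St3gal4 (-4.34 ± 0.31, 0.000435), Pam, an enzyme that amidates peptide hormones (-3.27 ± 0.46, 0.0150), Pdxdc1 on another probe set, Mtmr7, 0610005C13Rik (-2.52 ± 0.29, 0.00545), Snhg6, Ctsc, Meg3 (-2.42 ± 0.35, 0.0151), Rgs5 and B4galnt2. On other probe sets Ctsc gave 0.11, Rgs5 -0.52, B4galnt2 -0.95 and Slpi 3.35, 0.17 and 0.25. Glo1 was higher by 1.33 ± 0.18 (0.0128) and by 0.92 on its other probe set, and Nnt had 0.31 ± 0.25 (0.937). Of 21 named probe sets past the threshold, 18 kept their call without each of the 8 pools in turn, and Pam, Meg3 and Glo1 lost theirs without at least 4 of the pools, with adjusted p up to 0.0845, 0.0808 and 0.0809. The count was 42 and 39 without the sample 1 and sample 2 C57BL/6J wild-type pools, 39 and 49 without those of C3H/HeJBir, and 40 without the sample 1 C57BL/6J Il10-null pool.

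For this average, acute-phase and antimicrobial genes were higher by a median log2 of 0.81 over 14 members (camera adjusted p = 1.18e-10) and type I interferon-induced genes by 0.89 over 11 (3.86e-09), with an adjusted p of 0.728 for each with an estimated correlation. Interferon-gamma-induced genes were higher by 0.54 over 15 (6.50e-07), plasma cell and immunoglobulin genes by 0.55 over 9 (0.000142) and macrophage and dendritic cell markers by 0.13 over 15 (0.0104), again with 0.728 for each with an estimated correlation. So were MHC class I and antigen processing genes by 0.33 over 10 (0.0117) and MHC class II genes by 0.70 over 7 (0.0201). H2-D1, an MHC class I gene, gave 1.87 on the called probe set and -0.08 and -0.26 on brighter ones, the brightest of which was read for the list. Strain variants under the probes were not tested for these lists. Immediate early and heat shock genes were lower by -0.15 over 21 (0.0327). With an estimated correlation the adjusted p was 0.746 for the MHC lists and 0.728 for the immediate early list. Adjusted over the list alone, 5, 6, 1, 4 and 1 members of the lists from acute-phase to macrophage genes were higher and 0 of the MHC and immediate early lists passed. Ifi204, induced by interferon, had a difference of 1.63 ± 0.49, Ighg3 of 3.01 ± 0.56 and Lyz2 of 1.00 ± 0.29. The MHC class II call ended with the day as a block (camera adjusted p = 0.0544), with a median still at 0.70. Those of MHC class II, MHC class I, macrophage and immediate early genes ended without the sample 1 C57BL/6J Il10-null pool (medians 0.32, 0.25, 0.11 and -0.13). The first 3 of these also ended without the sample 1 C3H/HeJBir Il10-null pool (medians 0.39, 0.11 and 0.09). Further calls that ended were those of MHC class II and MHC class I without the sample 2 C3H/HeJBir wild-type pool (medians 0.56 and 0.35). So did those of MHC class II and immediate early genes without the sample 2 C57BL/6J wild-type pool (0.55 and -0.17). The immediate early call ended as well without the sample 1 C3H/HeJBir wild-type (-0.14) or sample 2 C3H/HeJBir Il10-null pool (-0.05). Over all alternatives of the 8 lists the adjusted p ranged from 1.77e-13 to 0.864. The medians ran from 0.18 to 1.02 for interferon-gamma-induced, from 0.31 to 1.18 for acute-phase, from 0.57 to 1.25 for type I interferon-induced and from 0.31 to 0.79 for plasma cell genes. The lowest of the first 3 was the value without the sample 1 C3H/HeJBir Il10-null pool.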

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

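The block on the hybridisation day for gene lists was chosen after the results were seen, and the other tests were planned. A pair of gene lists was called in a test of the difference between the strains' Il10 effects, with the preset correlation and not with an estimated one (adjusted p = 0.995 for each). Genes induced by type I interferon had a median log2 difference of -0.98 between the strains' Il10 effects (11 genes, camera adjusted p = 0.000139, and 0.995 with an estimated correlation). Genes of cholesterol synthesis had a median log2 difference of 0.45 (14 genes, camera adjusted p = 0.000630, and 0.995 with an estimated correlation). With a block on the day the adjusted p was 0.000455 for each, with the sample number as a block 0.000642 and 0.00113, in ranges over all alternatives from 4.92e-15 to 0.995 and from 0.000141 to 0.995.

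The type I interferon genes started from a higher level in the C3H/HeJBir wild-type pools, at 0.87 and 0.66 in median log2 deviation, against -0.40 and -0.67 in C57BL/6J wild type. In the Il10-null pools they stood at 0.57 and -0.40 in C3H/HeJBir and at -0.54 and -0.14 in C57BL/6J. The difference thus shared the C3H/HeJBir wild-type pools with the strain difference of this list in wild type. Leaving out either of those wild-type pools did not end its call. The call rested on the sample 2 Il10-null pools: without that of C3H/HeJBir the median was -0.11, and without that of C57BL/6J -0.65. Cholesterol synthesis genes stood at -0.52 and -0.15 in C3H/HeJBir wild type and at 0.44 and 0.06 in C3H/HeJBir Il10-null pools. Without the sample 1 C3H/HeJBir Il10-null pool their difference was 0.24 (0.140), without the sample 1 C3H/HeJBir wild-type pool 0.32 (0.185), and without the sample 2 C57BL/6J wild-type or Il10-null pool 0.39 (0.0772) or 0.37 (0.0995). The behaviour of the preset correlation on these lists and this comparison was not simulated. For another list and comparison, the 15 interferon-gamma-induced genes and the Il10 effect in C57BL/6J, an unshifted list whose members shared the deviations of the pools at a correlation of 0.624 was called in 39% of simulations.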

How the results depend on the processing

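The alternative without chromosomes 1, X and Y and, for gene lists, the block on the hybridisation day were chosen after the data were seen. Leaving out a pool leaves a lone pool in its group, which is assumed to vary like the others, and a fit of the compared groups only was not run for comparisons over all 4 groups, where it changes nothing. The number of arrays limits every result. Of 60 named results past the threshold, 986 of 1211 alternatives kept direction and call, 222 lost the call and 3 reversed. Of 38 named results not past it, 749 of 763 alternatives stayed so, 4 passed and 10 reversed. Of 49 called list results, 546 of 735 alternatives kept the call, 183 lost it and 6 reversed. Where no construction is named below, the cause was not tested.

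With a correlation estimated per list, and with fry, 0 lists were called in each of the 7 comparisons, where camera at the preset called 7 and 9 for the Il10 effect in C57BL/6J and C3H/HeJBir, 2 for the difference, 5 and 6 for the strain effect in wild type and Il10-null, and 12 and 8 for the average Il10 and strain effects. For the Il10 effect in C57BL/6J, limma called 1 probe set in place of 0 with the pseudocount at the 50th percentile, with a filter at the 60th percentile and with trend and robust moderation. For the Il10 effect in C3H/HeJBir it called 0 in place of 1 with the pseudocount at the 5th percentile, no filter, median scaling, a fit of the compared groups, a block on the day and averaged probe sets, and 0 by construction without chromosomes 1, X and Y, since Gas5 lies on chromosome 1. At an unadjusted p under 0.05 these comparisons had 118 and 211 probe sets.

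The 30 calls of the strain effect in wild type became 53 with the pseudocount at the 50th percentile, 51 with trend and robust moderation, 49 with a fit of the compared groups and, by construction, 46 at a threshold of 0.1. The 22 calls in Il10-null pools became 45, 45, 12 and 44 in the same order, 14 without a filter, 6 with a block on the day and 13 genes with averaged probe sets. A block on the day left 20 calls for the strain effect in wild type, of which 19 were among the 30. With the day as a block, 3 lists were called for the Il10 effect in C57BL/6J. With the sample number as a block, 0, 1, 0, 31, 23, 0 and 96 probe sets and 7, 10, 2, 4, 5, 12 and 9 lists were called over the 7 comparisons. This ended the calls of MHC class I in wild type (adjusted p = 0.0817), plasma cell genes in Il10-null pools (0.0692), Gbp2b in wild type (0.0891) and in Il10-null pools (0.0518) and Ergic1 in Il10-null pools (0.0518), and no other call named here. It added goblet cell markers in C3H/HeJBir (0.0398) and adipocyte markers for the average strain effect (0.0339).

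With the probe sets of a gene averaged, Pdxdc1, lower in C3H/HeJBir on the named probe set, had 0.33 in wild type, 0.34 in Il10-null pools and 0.34 on average, by construction, since the mean took in the probe set that was higher. The direction of further results changed with a pool left out. For the Il10 effect in C3H/HeJBir the values ran from -0.039 to 0.73 for MHC class I, from 0.020 to 0.72 for acute-phase genes, where the direction of the test changed, from -0.66 to 0.014 for enteroendocrine genes and from -0.26 to 1.82 for Pla2g2a. For the strain effect in Il10-null pools they ran from -0.17 to 1.23 for interferon-gamma-induced and from -0.24 to 1.07 for type I interferon-induced genes. For the difference between strains they ran from -0.20 to 0.51 for Cd14, from -0.061 to 1.39 for Gbp2b and from -0.71 to 1.37 for Pla2g2a. The first of each pair but that of enteroendocrine genes, and there the last, was the value without the sample 1 C3H/HeJBir Il10-null pool. The Pla2g2a difference was also -0.50, -0.07 and -0.06 without the sample 1 C57BL/6J wild-type, sample 1 C57BL/6J Il10-null or sample 2 C3H/HeJBir wild-type pool. The average Il10 effect of type I interferon-induced genes ran from -0.53 to 0.045, the latter without the sample 2 C3H/HeJBir Il10-null pool. In C57BL/6J, Pla2g2a ran from -0.38, without the sample 2 wild-type pool, to 1.28, and Gbp2b from -0.31, without the sample 2 Il10-null pool, to 0.78, with -0.29 without the sample 2 wild-type pool.

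Over the pools left out in turn, the calls ran from 0 to 0 for the Il10 effect in C57BL/6J, from 0 to 7 in C3H/HeJBir and from 0 to 0 for the difference. They ran from 2 to 39 for the strain effect in wild type, from 4 to 34 in Il10-null pools, from 0 to 11 for the average Il10 effect and from 39 to 106 for the average strain effect. The lists called ran, in the same order, from 3 to 13, 7 to 14, 0 to 12, 5 to 7, 1 to 15, 9 to 15 and 4 to 11.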

Other observations

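The test of female animals in the sample 1 pools was chosen after the result was seen, and the other tests were planned. Lists of genes for several cell types passed in no comparison with the planned test, and the smallest camera adjusted p of each over the 7 comparisons is given here. It was 0.0518 for smooth muscle, 0.0601 for goblet cell, 0.0601 for enteric neuron and glia, 0.289 for fibroblast, 0.825 for endothelial, 0.309 for skeletal muscle and 0.262 for absorptive colonocyte genes. With the sample number as a block, goblet cell markers passed in C3H/HeJBir (adjusted p = 0.0398). The smallest value was 0.287 for small intestinal and Paneth cell, 0.461 for exocrine pancreas, 0.0973 for chemokine, 0.0978 for cell cycle, 0.172 for ribosomal, 0.192 for oxidative phosphorylation and 0.412 for circadian clock genes and 0.198 for the neighbours of Il10 on chromosome 1. Lists with fewer than 5 tested genes were not tested. Their median log2 differences for the average Il10 and strain effects were 0.66 and 0.68 for 3 neutrophil genes, -0.18 and 0.72 for 3 Th1 and Th17 cytokines, 0.08 and 0.21 for 4 Th2 and regulatory genes and -0.10 and -0.06 for 3 eosinophil and mast cell genes. They were 0.00 and 0.37 for 4 sex-linked genes, 0.58 and 2.62 for 4 genes that differ between the strains' genomes, and 0.61 and 3.9 for the 3 genes put forward by the published study.

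In the comparison of sample numbers, 7 probe sets were higher and 4 lower in sample 2 pools (limma). Besides Xist these included Irs2, which transmits insulin signals (log2 2.65, adjusted p = 0.0272), Cdkn1a, an inhibitor of the cell cycle (1.46, 0.0378), Actb, beta-actin (1.67, 0.0378), and Sgpp1, which degrades sphingosine phosphate (-1.58, 0.0329), named after their values were seen. Fatty acid oxidation genes were higher by a median of 0.22 in sample 2 pools (camera adjusted p = 0.00788) and adipocyte markers lower by -0.52 (0.0311), with an adjusted p of 0.978 for each with an estimated correlation. One candidate explanation is that the sample 1 pools held female animals, which the labels do not give. Xist was higher and Eif2s3y lower in the sample 1 pool in 4 of 4 groups, but Eif2s3y was still at 39.7 to 318 in sample 1 pools, so that pools of both sexes are also open. These readings split by strain, at 39.7 and 113 in C57BL/6J and 318 and 242 in C3H/HeJBir. In the sample 2 pools they were 256 and 263 in C57BL/6J and 411 and 391 in C3H/HeJBir. Whether the mix of sexes differed between the strains was not tested. Of the called probe sets with a known chromosome, 88.9%, 8 of 9, lay on autosomes. Only 191 of the 7453 tested probe sets were placed on the X chromosome, so this share would be high under any cause and decides nothing. Sex as the whole cause is argued against by the 5th percentile of intensity, 3.3 to 3.8 on sample 1 and 1.99 to 2.55 on sample 2 arrays. The sample number also followed the hybridisation year, from which it cannot be told apart.

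On chromosome 1, where Il10 lies, the C3H/HeJBir Il10-null pools differed from wild type more often than on the other chromosomes pooled, but not more often than on chromosome 8 (5.08% against 5.15%). A candidate explanation is DNA of another strain carried along with the targeted allele. It was set to need an odds ratio above 1 with p under 0.05, which was met (1.93, Fisher's exact test, p = 0.0131). It was also set to need a slope of the Il10 difference on the strain difference lower on chromosome 1 than on each other chromosome. This was not met, at -0.0941 on chromosome 1, rank 2 of 20 chromosomes with a lowest other value of -0.169. The slope still lay below the median of the other chromosomes, 0.132, the limit set against the explanation. Not deciding are the share on chromosome 8 and the odds ratio of 1.66 for the 100 probe sets nearest to Il10 (Fisher's exact test, two-sided, p = 0.295). That window stopped short of Cacna1e, Acbd6, Qsox1, Tor3a and Gas5, which lay 53.5 to 71.5 probe sets from Il10 on 1 side. It also left out Lactb2, Xrcc5, Eif4e2, Itln1 and Atf3 elsewhere on the chromosome. It is thus a weak test of nearness, and a window fitted to these genes would be chosen after their values were seen. A response to the loss of Il10 shared by both strains is the biological alternative, and 61.1% of these probe sets had the same sign in C57BL/6J, against 69.2% of those on other chromosomes. These explanations cannot be told apart, since 18 probe sets are few and no genotypes along the chromosome were used here.

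Many strain calls rested on single probe sets. A candidate explanation is that strain variants under the probes, or a change in part of the transcript, alter the signal of a probe set without a change in the level of the whole gene. Of 28 other tested probe sets of 20 genes called for the average strain effect, 28.6% had the same sign and at least 50% of the log2 size, 20 had the same sign, and 2, both of Pdxdc1, were past the threshold in the opposite direction. The called probe sets were chosen for passing on these same pools, which by itself favours smaller differences on the others. B4galnt2, at -0.95 ± 0.18 on its other probe set, counts as not reaching 50%. The share of 28.6% can thus be low without any variant under the probes. Among those at least as bright as the called one the share was 23.1% (3 of 13, exact 95% binomial interval 5.04 to 53.8). The choice of the called probe sets lowers this share too. It therefore does not decide whether the other probe sets were too dim to show the change. The interval treats the 13 as independent and is too narrow, since several belonged to Ighm or to H2-D1. The 3 bright probe sets with the same sign and at least 50% of the log2 size were those of Ighm and Meg3. For 47 called genes no other probe set was tested, and a difference in the level of the gene stays open for them.

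The averages were compared with the other ways to divide the 8 pools into 4 and 4, in a fit of 2 groups. For the average Il10 effect, with 0 probe sets called by limma (230 at an unadjusted p under 0.05 in the model of 4 groups), 35 of the 35 splits called at least as many, the highest other 125. A count of 0 fixes this outcome, so it says nothing about chance. For the average strain effect, 113 were called, and 2 of the 35 splits called as many, the real one included, so chance is not excluded by this count. The highest other, 125, was the split by sample number, which points to a structure of the samples, and 33 splits called none. Among the 18 splits with 2 pools of each sample number on each side, the highest other called 0, and with the sample number as a block 96 probe sets were called for strain.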
